A study of Homo sapiens with 23 samples.

How the data were processed

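Exosomes were isolated from plasma with a precipitation reagent and their RNA was made into multiplexed small RNA libraries that were sequenced on a HiSeq 2000, per the labels' protocols. The 23 libraries form 1 group, each from a separate patient, and were numbered in accession order, which gives no pairing. The labels give no outcome, batch or treatment for a library.

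One deposited table gives read counts per library: raw reads, query reads, mappable reads and 10 RNA classes. In all 23 libraries the classes sum exactly to the mappable total. Query reads were 76.6% ± 5.94 of raw reads and mappable reads 67.4% ± 6.66 of query reads (SD, n = 23). The other deposited table gives a log2 level for 432 rows, 375 known miRNAs and 57 predicted loci, per the file headers. The aligner, the miRNA database release, the genome build and the adjustment behind these levels are not given in the sources used here. Summed as powers of 2, the levels of a library come to 971030 to 1035328, so a linear level was read as close to a CPM value. They are not whole reads: floor values are shifted by library, and libraries fell into 7 sets of 3 to 4 with nearly equal floors (median difference 0.0227 within and 1.03 log2 units between sets, average linkage on 27 predicted loci). The sets were found in the data and are not the study's groups. The percent column that the authors deposited matched, within 0.005 percentage points in all 432 rows, each row's share of the summed log2 levels, so it is not a share of reads and was not used. One predicted locus was left out because of its chromosome, which left 56 predicted loci and 431 rows.

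Share of the profile means the linear level over the sum of linear levels in that library. The depth behind a level is known only as the total of mature miRNA reads, 1830798 to 3734717 per library, and no interval was given for single miRNAs. The Wilson interval (95%) was computed for class shares. Intervals cover counting error only.

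A count test with TMM scaling had been planned. Because counts per miRNA are not in the tables used, limma (version 3.58.1, R 4.3.3) with an intensity trend and robust moderation replaced it, fitted to the deposited log2 levels of known miRNAs with no pseudocount, on the z-scored log2 level of miR-375, of miR-1290 or of the red cell index (miR-451a over miR-23a-3p). The covariate miRNAs were left out of the calls. Calls have a Benjamini-Hochberg adjusted p under 0.05. Slopes are log2 units per SD of the covariate. Gene lists were tested within each screen with camera, with a preset correlation of 0.01 and again with an estimated one. In 20 simulated data sets of 375 miRNAs for the miR-375 screen, 20.7%, 74.5% and 98.5% of miRNAs given slopes of 0.1, 0.25 and 0.5 were recovered, and 3.49% of calls were false. The simulated noise was independent between miRNAs and its SD was capped, so these rates need not hold for the screens.

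Values within a library were compared by sign-flip permutation tests and correlations by permutation, both two-sided with 100000 resamples, whose smallest p is 1e-05. Co-variation of a list is the mean Spearman correlation between its members (1 arm per hairpin), against 10000 random lists matched on mean level, one-sided. On 200 simulated lists of 8 members, 6.5% of unrelated lists and 100% of lists with a shared factor were called. Noise in these lists was independent between miRNAs and the shared factor had the SD of the noise, so weaker sharing was not covered. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Hairpin and U2 snRNA sequences were taken from the GENCODE transcripts of the reference annotation, used for sequence only.

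The lists, the planned tests and the rule for named miRNAs were fixed before the data were examined. That plan did not hold camera, adjustment over a list alone, tests between library sets or shuffled orders of a covariate. The lists were study candidates, let-7, miR-30, red cell, platelet and myeloid, lymphoid, liver, epithelial, prostate cancer in plasma, smooth muscle and stroma, striated muscle, neural and endocrine, placental and embryonic, and the clusters of miR-17/92, of miR-183 and miR-182, and of 14q32; a list needed 3 listed members for a test. Named were the 20 most abundant miRNAs, the candidates, up to 4 leading members of each list, up to 15 calls per direction and screen with the smallest adjusted p, and the 5 most and 5 least variable miRNAs for their level. References were the let-7 and miR-30 families, since the study's own are not named in the sources used here. Alternatives were scaling, filters, added constants, second covariates, left-out libraries, ranks and other references. Survival and the follow-up cohort were not analysed here.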

Results

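Small RNA was sequenced from plasma exosomes, the small membrane vesicles that cells release into blood, in castrate-resistant prostate cancer, the stage at which the tumour progresses although androgen signalling is suppressed. There was 1 group of 23 libraries, each from a separate patient, and the libraries carried no outcome, treatment or batch label. Per the series title, the study asked whether exosomal miR-1290 and miR-375 mark prognosis; survival and the qRT-PCR follow-up were not analysed here. Comparisons were therefore made between RNAs within a library and across the 23 libraries. The libraries held 12979382 ± 1191371 raw reads (SD, n = 23; range 10944016 to 16107199), of which 6673996 ± 792390 were mappable (4510521 to 7775779) and 2784360 ± 522267 were mature miRNA reads (1830798 to 3734717).

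Mature miRNA was the largest RNA class in these exosomes, with 41.5% ± 4.63 of mappable reads (SD, n = 23; range 33.8% to 49.3%). It lay 1.01 ± 0.43 log2 units above piRNA, the germline-associated small RNA class, and was the higher of the pair in 23 of 23 libraries. The piRNA class (20.9% ± 4.27) and long non-coding RNA (20.3% ± 2.44) took similar shares, and neither was reliably the higher. Fragments of mRNA held 6.59% ± 1.43, tRNA 3.81% ± 0.915, pseudogene transcripts 3.10% ± 1.4 and unprocessed (premature) miRNA 2.72% ± 0.240. The spliceosomal snRNAs held 0.937% ± 0.322, snoRNA, which guides the modification of ribosomal RNA, 0.0893% ± 0.0125, and ribosomal RNA 0.00147% ± 0.00080, or 18 to 187 reads per library.

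Of the 9 pairs of neighbouring classes, 7 differed in a two-sided sign-flip permutation test of the log ratio within libraries (Benjamini-Hochberg adjusted). For 6 of these the adjusted p was 1.5e-05, from the smallest p the permutations can give (1e-05). The tRNA class exceeded pseudogene transcripts by 0.36 ± 0.62 log2 units in 18 of 23 libraries (adjusted p = 0.0151), but over the means of the 7 library sets described next this was lost (0.36 ± 0.46 log2 units, higher in 5 of 7 sets; exact sign-flip p = 0.109, adjusted p = 0.141). The other 6 differences held in all 7 sets (exact sign-flip p = 0.0156, the smallest that 7 sets allow; adjusted p = 0.0234). The piRNA class was above long non-coding RNA in 13 of 23 libraries (adjusted p = 0.758), and pseudogene transcripts were above premature miRNA in 12 of 23 (adjusted p = 0.549). The widest 95% Wilson interval of a library's mature miRNA share was ± 0.0453 percentage points and covers counting error only.

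The libraries fell into 7 sets of 3 to 4 that shared the floor values of the miRNA table, and several RNA classes differed between these sets. The share of variance lying between sets was 95.1% for snRNA, 90.2% for piRNA, 81.7% for tRNA, 77.8% for snoRNA and 68.6% for mRNA (permutation test with 2000 permutations, adjusted p = 0.0010 for each, from the smallest p they can give). It was 64.1% for mature miRNA (adjusted p = 0.0158). Ribosomal RNA (50.7%, adjusted p = 0.0764), premature miRNA (39.1%, 0.224), pseudogene transcripts (34.9%, 0.241) and long non-coding RNA (28.1%, 0.427) did not pass. Of the 375 known miRNAs, 0 differed between sets after adjustment of the F test and 44 had an unadjusted p under 0.05.

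**Figure D1:**
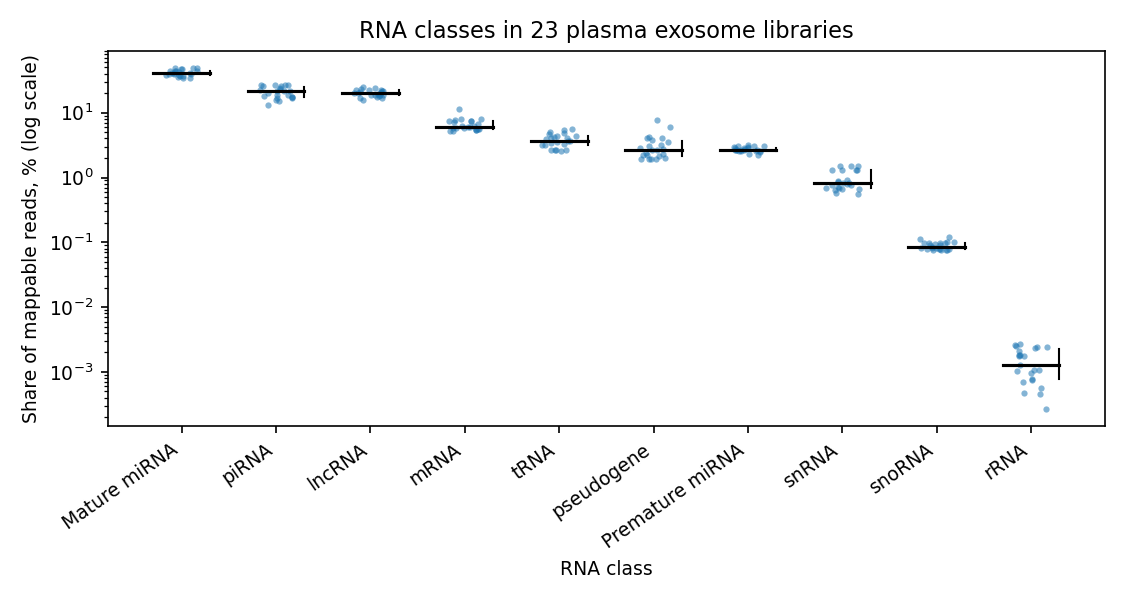
Share of mappable reads (%, log scale) for 10 RNA classes; each point is 1 of 23 plasma exosome libraries, horizontal lines are medians and vertical lines interquartile ranges. Mature miRNA lies highest, at 33.8% to 49.3%, and ribosomal RNA lowest, at a mean of 0.00147%.

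The miRNA profile was dominated by a few miRNAs. Alone, miR-99a-5p, a miRNA abundant in smooth muscle, stroma and many other tissues, held 14.4% ± 1.18 of the profile (SD, n = 23). It was followed by 2 miRNAs enriched in neurons, miR-128 (5.95% ± 1.19) and miR-129-5p (5.27% ± 0.986). Next came miR-22-3p (4.97% ± 1.04), the neural miR-9-3p (4.66% ± 0.592), miR-181a-5p (4.01% ± 0.489), which acts in lymphocyte development, and miR-100-5p (3.82% ± 0.311), a relative of miR-99a. The 10 most abundant miRNAs also included miR-320a (3.70% ± 1.14), miR-181b-5p (3.64% ± 0.285) and let-7i-5p (3.11% ± 0.441).

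Together the 10 most abundant known miRNAs held 53.5% ± 3.11 of the profile and the 20 most abundant 70.4% ± 2.74 (n = 23). Ranks 11 to 20 were miR-9-5p (2.59%), the oncogenic miR-21-5p (1.98%), let-7b-5p (1.90%), miR-30d-5p (1.74%), miR-101-3p (1.69%), the neuronal miR-124-3p (1.49%), miR-27b-3p (1.44%), miR-99b-5p (1.41%), miR-30a-5p (1.33%) and miR-24-3p (1.29%).

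Detection was close to complete for the listed miRNAs. The linear level, 2 to the power of the deposited value, sums to between 971030 and 1035328 in a library. All 375 known miRNAs had a linear level of at least 1 in every library, 333 of at least 5, 298 of at least 10, 159 of at least 100 and 62 of at least 1000. A single library had 333 ± 6.06 known miRNAs at 10 or more (SD, n = 23). These numbers describe the rows of the table, which lists known miRNAs only at 1 or above in every library.

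By preset list, the 9 neural and endocrine miRNAs held 21% ± 1.39 of the profile (SD, n = 23, range 18.3% to 24.0%). The 8 of smooth muscle and stroma held 20.8% ± 1.49, led by miR-99a-5p, miR-100-5p and miR-143-3p (1.08% ± 0.191). From which tissue the listed miRNAs came was not tested. Platelet and myeloid miRNAs held 9.20% ± 0.823, led by miR-22-3p and miR-21-5p. Lymphoid miRNAs held 8.26% ± 0.705, mostly miR-181a-5p and miR-181b-5p, with miR-146a-5p, a brake on inflammatory signalling, at 0.150% ± 0.0130. The red cell list held 2.27% ± 2.16 and ranged from 1.05% to 11.1%, with miR-92a-3p at 0.872% ± 0.287 and the erythroid miR-451a at 0.725% ± 1.43 (0.452% ± 0.60 without its highest library, n = 22). The liver list held 0.356% ± 0.30, most of it the hepatocyte miRNA miR-122-5p (0.254% ± 0.285).

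Among family lists, let-7, a family of differentiation-associated miRNAs, held 6.02% ± 0.705 and miR-30 held 4.08% ± 0.281. The imprinted 14q32 cluster held 5.03% ± 0.287, led by miR-433 (1.23% ± 0.186) and miR-127-3p (0.789% ± 0.151), and the proliferation-associated cluster miR-17/92 held 0.908% ± 0.298, almost all of it miR-92a-3p. The list reported for prostate cancer in plasma held 3.95% ± 0.262, led by miR-21-5p and miR-378a-3p (1.20% ± 0.227). Striated muscle miRNAs held 0.0827% ± 0.0112, led by miR-206, and the epithelial list 0.0403% ± 0.00631, most of it miR-200a-3p (0.0340% ± 0.00534). The cluster of miR-183 and miR-182 held 0.00593% ± 0.00410, and 0 of 20 placental and embryonic miRNAs were listed. Lists overlap, since miR-375, miR-92a, miR-21, miR-199a, miR-200b, miR-200c and miR-409 stand in more than 1 of them, so the shares do not add up.

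**Figure D2:**
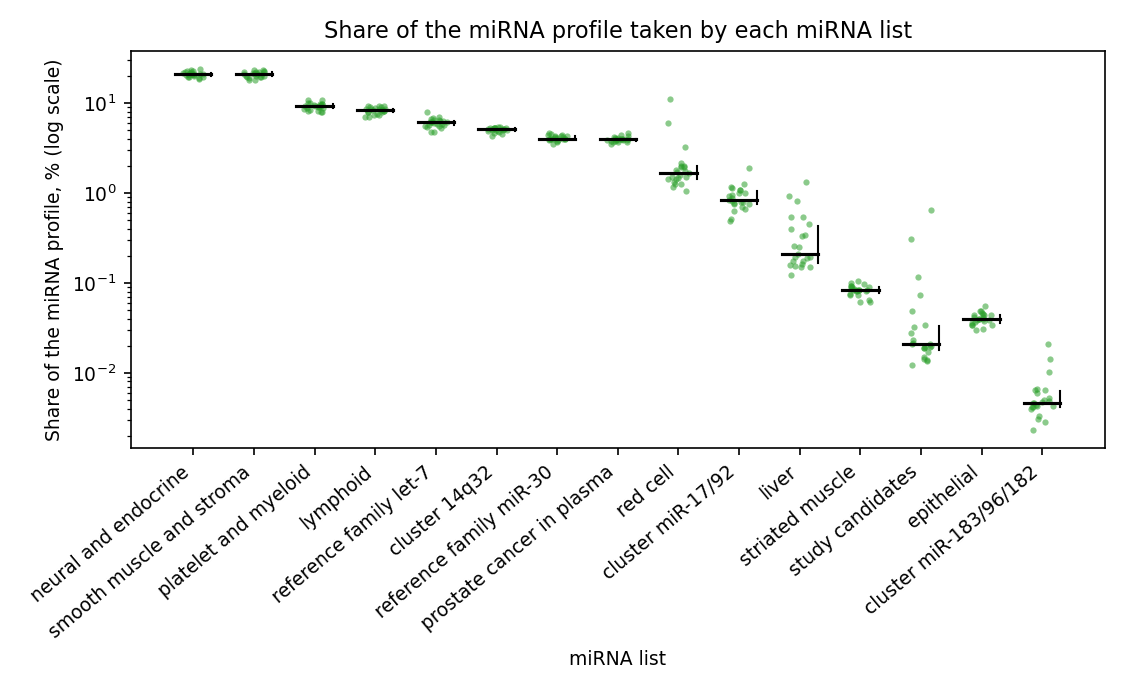
Share of the miRNA profile (%, log scale) held by each miRNA list; each point is 1 of 23 libraries, horizontal lines are medians and vertical lines interquartile ranges. The neural and endocrine list stays between 18.3% and 24.0%, while the red cell list spans 1.05% to 11.1%.

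Known miRNAs had a median SD of 0.30 log2 units between patients, and a small number differed far more. By SD for their level, the 5 most variable known miRNAs were miR-451a (SD 1.42 log2 units, n = 23), miR-486-5p (1.49), miR-122-5p (1.36), miR-1246 (1.52) and miR-375 (1.42). The first pair is erythroid, miR-122-5p is made in the liver, and miR-375 is an endocrine and epithelial miRNA raised in prostate tumours. Between the lowest and the highest library miR-451a differed 56.9-fold, miR-486-5p 53.4-fold, miR-375 56.4-fold, miR-1246 39.8-fold and miR-122-5p 34.9-fold. Without the highest library of each these ranges were 24.3-fold, 42.6-fold, 23.4-fold, 26.3-fold and 22.8-fold, in the same order. The least variable for their level were miR-30e-5p (0.08), miR-151b (0.18), miR-129-2-3p (0.10), miR-221-3p (0.09) and miR-151a-5p (0.14).

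**Figure D3:**
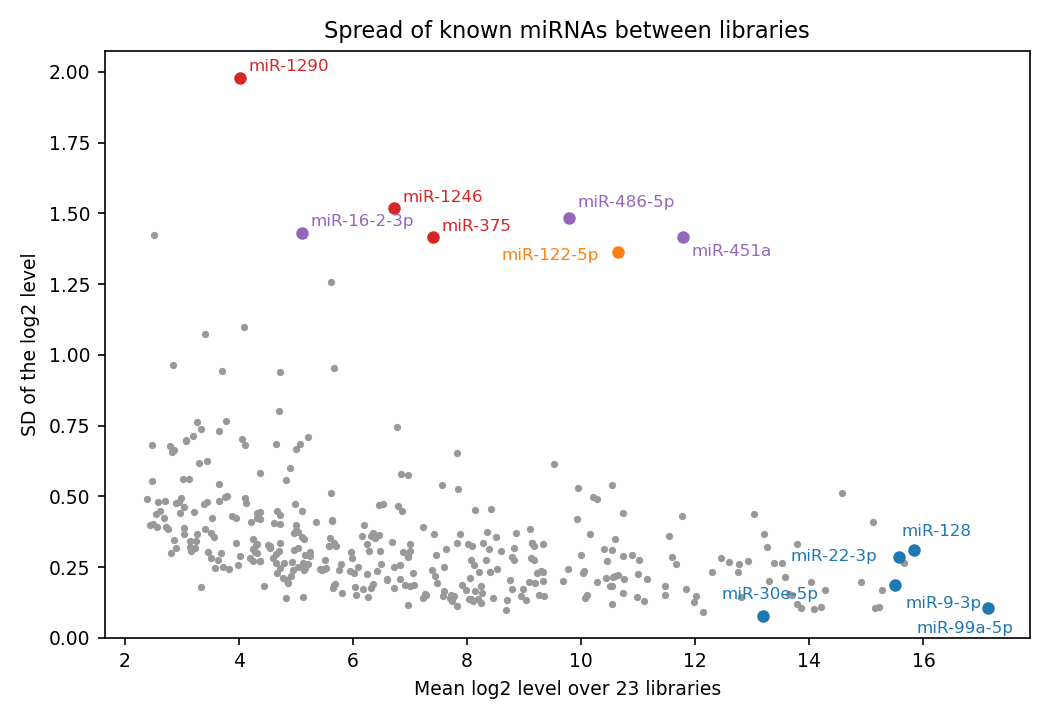
SD of the log2 level against the mean log2 level of 375 known miRNAs over 23 libraries, each point 1 miRNA; candidates are red, erythroid miRNAs purple, miR-122-5p orange and abundant or low-spread miRNAs blue. The candidates miR-1290, miR-1246 and miR-375 have SDs of 1.98, 1.52 and 1.42, whereas miR-99a-5p, the most abundant, has 0.11.

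The candidates lay below the families usually used as references and varied more than most members of these families. The log2 level of miR-375 was 7.41 ± 1.42 (SD, n = 23), that of miR-1246, included beside them, 6.71 ± 1.52, and that of miR-1290 4.01 ± 1.98, against 10.78 ± 0.27 for the mean of 14 let-7 and miR-30 members. Relative to these references miR-375 was 10.3-fold lower and miR-1246 16.7-fold lower, and miR-1290 was 109-fold lower. All 3 candidates together held 0.0671% ± 0.139 of the profile, or 0.0411% ± 0.0633 without the highest library (n = 22). Their SDs stood against a median of 0.43 for let-7 and 0.15 for miR-30 members. Each had a larger SD than all of the 50 known miRNAs nearest to it in level.

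The log2 ratio to the references was -3.37 ± 1.44 for miR-375 (below in 21 of 23 libraries), -4.07 ± 1.57 for miR-1246 (23 of 23) and -6.77 ± 1.98 for miR-1290 (23 of 23). Each had an adjusted p of 1.2e-05 in the two-sided sign-flip permutation test, adjusted over 6 ratios, from the smallest p the permutations can give (1e-05). Between candidates, miR-375 exceeded miR-1246 by 0.70 ± 0.75 log2 units (adjusted p = 0.00044; lower in 5 of 23 libraries). It exceeded miR-1290 by 3.40 ± 1.22, and miR-1246 exceeded miR-1290 by 2.70 ± 0.73, both in 23 of 23 libraries (adjusted p = 1.2e-05).

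The candidates rose and fell together across patients. Pearson's r was 0.945 between miR-1290 and miR-1246, 0.871 between miR-375 and miR-1246 and 0.791 between miR-1290 and miR-375 (n = 23). Spearman's rho was 0.888, 0.764 and 0.731, in the same order. All 3 also rose with the share of pseudogene reads, the only one of 10 RNA classes to pass in 30 pairs, a relation examined after the data were seen. With its log2 share r was 0.633 for miR-375, 0.708 for miR-1246 and 0.751 for miR-1290 (n = 23; permutation p = 0.00368, 0.00039 and 6e-05, adjusted p = 0.0368, 0.00585 and 0.0018). The rho was 0.499, 0.669 and 0.670 (permutation p = 0.0159, 0.00071 and 0.00064, adjusted p = 0.159, 0.0107 and 0.0107), so by rank miR-375 did not pass. Without the 2 libraries farthest from the median share r was 0.608, 0.655 and 0.699, and within library sets it was 0.783, 0.713 and 0.715 (permutation adjusted p = 0.0120, 0.0350 and 0.0270). The relation was not limited to the candidates: by r within sets miR-375 ranked 1, miR-1290 6 and miR-1246 7 of 375 known miRNAs, and miR-192-5p (0.756), miR-185-5p (0.747), miR-19b-3p (0.727) and miR-191-5p (0.716) stood between them. In limma's test 6 of 375 known miRNAs rose with the pseudogene share and 0 fell, namely the candidates, miR-200c-3p, miR-21-3p and miR-345-5p, and with the library set as a factor 9 rose. Given the pseudogene share, the partial r over all libraries was 0.887 between miR-1290 and miR-1246, 0.773 between miR-375 and miR-1246 and 0.618 between miR-1290 and miR-375. Within sets it was 0.909, 0.825 and 0.754, in the same order. The hairpins of miR-1246 and miR-1290 share 17 bases with at most 1 mismatch, so the assignment of reads between them is uncertain.

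Of 15 pairs among the 3 candidates, the red cell index, log10 miRNA reads and the miRNA share of mappable reads, 4 passed the permutation test. The candidate pairs had p = 1e-05 for r, the smallest the permutations can give (adjusted p = 3.75e-05), and for rho p = 1e-05, 6e-05 and 0.00016 (adjusted p = 7.5e-05, 0.0003 and 0.0006). Without the 2 libraries farthest from the median of x, r was 0.918, 0.827 and 0.784, and given the library set the partial r was 0.955, 0.918 and 0.888. The fourth pair was miRNA reads with the miRNA share (r = 0.780, rho = 0.828, p = 1e-05 for both, adjusted p = 3.75e-05 and 7.5e-05). Its r was 0.829 without the 2 farthest libraries. The miRNA reads are the numerator of that share, so part of this relation was built in and the test does not allow for it. With the red cell index, r was -0.32 for miR-1290, -0.31 for miR-375 and -0.40 for miR-1246 (adjusted p = 0.242, 0.242 and 0.157), and rho was -0.35, -0.33 and -0.39 (adjusted p = 0.251, 0.268 and 0.195). None of these passed.

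**Figure D4:**
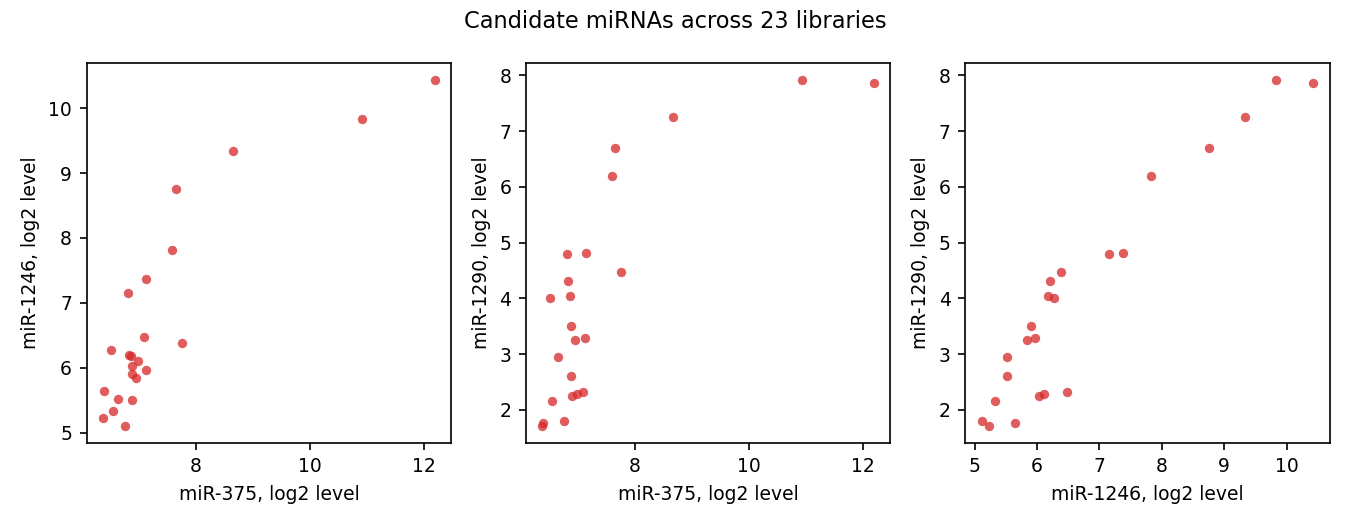
Log2 levels of miR-375, miR-1246 and miR-1290 plotted in pairs, each point 1 of 23 libraries. All 3 pairs rise together, with r of 0.871, 0.791 and 0.945 from left to right.

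Lists whose members varied together across patients were the candidates, let-7, red cell, miR-17/92, epithelial and liver miRNAs. The mean Spearman correlation between members was 0.794 for the 3 candidates (adjusted p = 0.00426 against 10000 random lists of matched level), of which miR-375 and miR-1290 were chosen by the study on these libraries, so it is not independent evidence. It was 0.650 for the 9 let-7 members (adjusted p = 0.00173) and 0.467 for the red cell list (0.0141), and 0.485 for cluster miR-17/92 (0.0270). The epithelial list, which holds miR-200 members that mark epithelial cells, reached 0.450 (0.0197) and the liver list 0.326 (0.0383).

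The other 8 of 14 lists did not pass this one-sided test. The mean correlation was 0.205 for miR-30 (adjusted p = 0.191), 0.135 for smooth muscle and stroma (0.191), 0.0979 for platelet and myeloid (0.210), 0.0761 for striated muscle (0.335), 0.0726 for the 14q32 cluster (0.207), 0.0608 for lymphoid (0.335), 0.0413 for prostate cancer in plasma (0.335) and -0.0480 for neural and endocrine (0.922). With a linear level of at least 10 required in every library, 3 lists passed: the candidate and epithelial lists kept fewer than 3 members and could not be tested, and liver did not pass (0.408, adjusted p = 0.179). With read depth and the red cell index regressed out 3 passed. The red cell list (mean correlation 0.268, adjusted p = 0.108), cluster miR-17/92 (0.381, 0.0876) and liver (0.343, 0.0582) were no longer among them. The index is built from miR-451a, a member of the red cell list. Regressing it out removes part of that list's shared variation by construction, so its lost call says little.

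Rising miR-375 went with 8 of 374 known miRNAs, all upward. With the library set as a factor 7 of these 8 calls remained. Per SD of miR-375 (1.42 log2 units), miR-1290 rose by 1.57 ± 0.25 log2 units (SE, n = 23) and miR-1246 by 1.32 ± 0.15. The pancreas-associated miR-217 and miR-216a-5p rose by 0.53 ± 0.09 and 0.51 ± 0.11, and the epithelial miR-200b-3p and miR-200c-3p by 0.53 ± 0.11 and 0.45 ± 0.10. The remaining calls were miR-345-5p (0.77 ± 0.15) and miR-184 (0.47 ± 0.12), a miRNA of eye and endocrine tissue. In limma's test, the adjusted p was 1.86e-06 for miR-1246, 0.000215 for miR-1290, 0.000444 for miR-217, 0.00321 for miR-345-5p, 0.00427 for miR-216a-5p, 0.00599 for miR-200b-3p, 0.0137 for miR-200c-3p and 0.0246 for miR-184.

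Of the 4 epithelial rows tested, 2 rose with miR-375, and 2 adjusted over the list alone (camera adjusted p = 0.000595 with a preset correlation). The list's call was lost at adjusted p = 0.0859 with an estimated correlation. The rises were those of miR-200b-3p and miR-200c-3p, at low mean log2 levels of 3.26 and 2.87. The more abundant miR-200a-3p (8.39) and miR-203a (5.42) did not pass (0.10 and 0.03 per SD, limma adjusted p = 0.520 and 0.994). Among the prostate cancer in plasma rows, 2 of 12 rose, and 3 adjusted over the list alone (camera adjusted p = 0.216). No member of the neural and endocrine (17 rows), let-7 (18), miR-30 (10), red cell (13), platelet and myeloid (18), lymphoid (12), liver (7), smooth muscle and stroma (15), striated muscle (4), miR-17/92 (5) or 14q32 (36) lists passed. Without the 2 libraries of most extreme miR-375 there were 6 calls, of which only miR-1246 and miR-1290 were among the 8, and by rank of miR-375 the same held (6 calls, 2 shared). Among the 297 miRNAs tested at a linear level of 10 or more in every library, 2 of the 8 calls remained. This filter removed miR-1290, miR-200b-3p and miR-200c-3p, which were therefore not tested again. With the red cell index as a second covariate 18 rose, and with the log2 pseudogene share 3 rose, miR-1246, miR-217 and miR-216a-5p. The rises of miR-200b-3p and miR-200c-3p then lost their calls (0.41 and 0.26, limma adjusted p = 0.407 and 0.785). Of 100 orders of miR-375, the real one included, 2 gave at least 8 calls (highest among the shuffled ones 10).

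With miR-1290, 6 of 374 known miRNAs rose and 0 fell. With the library set as a factor 8 rose, among them all 6. Per SD of miR-1290 (1.98 log2 units), miR-1246 rose by 1.44 ± 0.10 log2 units (SE, n = 23), miR-375 by 1.12 ± 0.18 and miR-345-5p by 0.72 ± 0.16. The epithelial miR-200b-3p and miR-200c-3p rose by 0.60 ± 0.10 and 0.47 ± 0.10, and miR-21-3p, the less abundant arm of the miR-21 hairpin, by 0.42 ± 0.10. In limma's test the adjusted p was 8.83e-11, 0.000310, 0.0149, 0.000336, 0.00891 and 0.0189, in the order named. The screens for miR-375 and miR-1290 shared 4 calls, miR-1246, miR-345-5p, miR-200b-3p and miR-200c-3p, and each called the other's covariate.

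The epithelial list rose with miR-1290 in 2 of 4 rows, and 2 adjusted over the list alone (camera adjusted p = 4.89e-05 with a preset and adjusted p = 0.0166 with an estimated correlation). These rows were again the scarce miR-200b-3p and miR-200c-3p, and miR-200a-3p, which holds most of the list, was not called. Prostate cancer in plasma miRNAs rose in 4 of 13 rows (miR-375, miR-200b-3p, miR-200c-3p and miR-21-3p), and 4 adjusted over the list alone (camera adjusted p = 0.000314; adjusted p = 0.00372 with an estimated correlation). Both lists share the miR-200 members. The prostate cancer in plasma list also holds miR-375, which the study chose together with miR-1290 on these libraries, so its result is not independent evidence. One row each of the neural and endocrine list (miR-375) and of the platelet and myeloid list (miR-21-3p) rose, and neither list passed (camera adjusted p = 0.982 and 0.181). There were 2 calls without the 2 libraries of most extreme miR-1290, 3 by rank, 2 among miRNAs at a linear level of 10 or more in every library, and 10 with the red cell index as a second covariate. The filter on level removed miR-200b-3p and miR-200c-3p, which were therefore not tested there. With read depth as a second covariate 4 remained, without miR-345-5p and miR-21-3p (limma adjusted p = 0.0559 and 0.0685), and with upper quartile scaling 5, without miR-21-3p (0.0570). With the log2 pseudogene share as a second covariate only miR-1246 remained; the slopes of miR-200b-3p and miR-200c-3p were then 0.60 and 0.29 (limma adjusted p = 0.125 and 0.877). Given miR-375, only miR-1246 passed, and given miR-1290, only miR-217 passed with miR-375. Of 100 orders of miR-1290, the real one included, 4 gave at least 6 calls (highest among the shuffled ones 77).

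Erythroid miRNAs rose together with the red cell index, the log2 ratio of miR-451a to miR-23a-3p that is used to detect haemolysis. The index averaged 1.25 ± 1.38 (SD, n = 23) and ranged from -0.22 to 5.44. Of 373 known miRNAs, 28 rose and 2 fell with it, and with the library set as a factor 25 rose and 6 fell. Per SD of the index, miR-486-5p rose by 1.43 ± 0.09 log2 units (SE, n = 23), miR-16-2-3p by 1.27 ± 0.13, miR-144-3p, made from the same erythroid transcript as miR-451a, by 0.84 ± 0.09, miR-363-3p by 0.48 ± 0.05 and miR-25-3p by 0.46 ± 0.05. The falls were miR-10b-3p (-0.29 ± 0.09) and miR-767-5p (-0.09 ± 0.03).

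In limma's test the adjusted p was 1.81e-12 for miR-486-5p, 4.67e-08 for miR-363-3p, 1e-07 for miR-16-2-3p, 1.52e-07 for miR-144-3p, 4.39e-07 for miR-25-3p, 0.0379 for miR-10b-3p and 0.0395 for miR-767-5p. Other rises were miR-584-5p (0.89), miR-15b-5p (0.76), miR-15b-3p (0.61), miR-20b-5p (0.57), miR-4508 (0.55), miR-142-5p (0.44), miR-15a-5p (0.37), miR-19a-3p (0.30), miR-106b-3p (0.27) and miR-484 (0.27), with adjusted p from 2.69e-05 to 0.000682. Of the red cell list, 7 of 12 rows rose, and 8 adjusted over the list alone (camera adjusted p = 3.78e-16; adjusted p = 0.000325 with an estimated correlation). All 5 rows of cluster miR-17/92 rose, and 5 adjusted over the list alone (camera adjusted p = 2.78e-06; adjusted p = 0.0297 with an estimated correlation). One lymphoid row (miR-142-5p) and one liver row (miR-194-5p) rose, and neither list passed (camera adjusted p = 0.872 and 0.779).

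None of the candidates passed with the red cell index, and this screen shared 0 calls with those for miR-375 and miR-1290. Of the 30 calls, miR-486-5p and miR-16-2-3p remained without the 2 libraries of most extreme index, whose removal lowered the SD of the index from 1.38 to 0.76. Per log2 unit of the index their slopes went from 1.03 ± 0.07 to 0.94 ± 0.12 (SE) and from 0.92 ± 0.10 to 0.86 ± 0.21. That of miR-144-3p went from 0.61 ± 0.07 to 0.41 ± 0.13, and it no longer passed (limma adjusted p = 0.368). There were 11 calls without the library of highest index alone, and 4 by rank of the index. Among miRNAs at a linear level of 10 or more in every library 19 passed, and with upper quartile scaling 31 rose and 0 fell. The falls of miR-10b-3p and miR-767-5p had lost their calls there (-0.25 and -0.05, limma adjusted p = 0.0874 and 0.551), as they did by rank and without the 2 libraries of most extreme index. Of 100 orders of the index, the real one included, 2 gave at least 30 calls (highest among the shuffled ones 102).

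**Figure D5:**
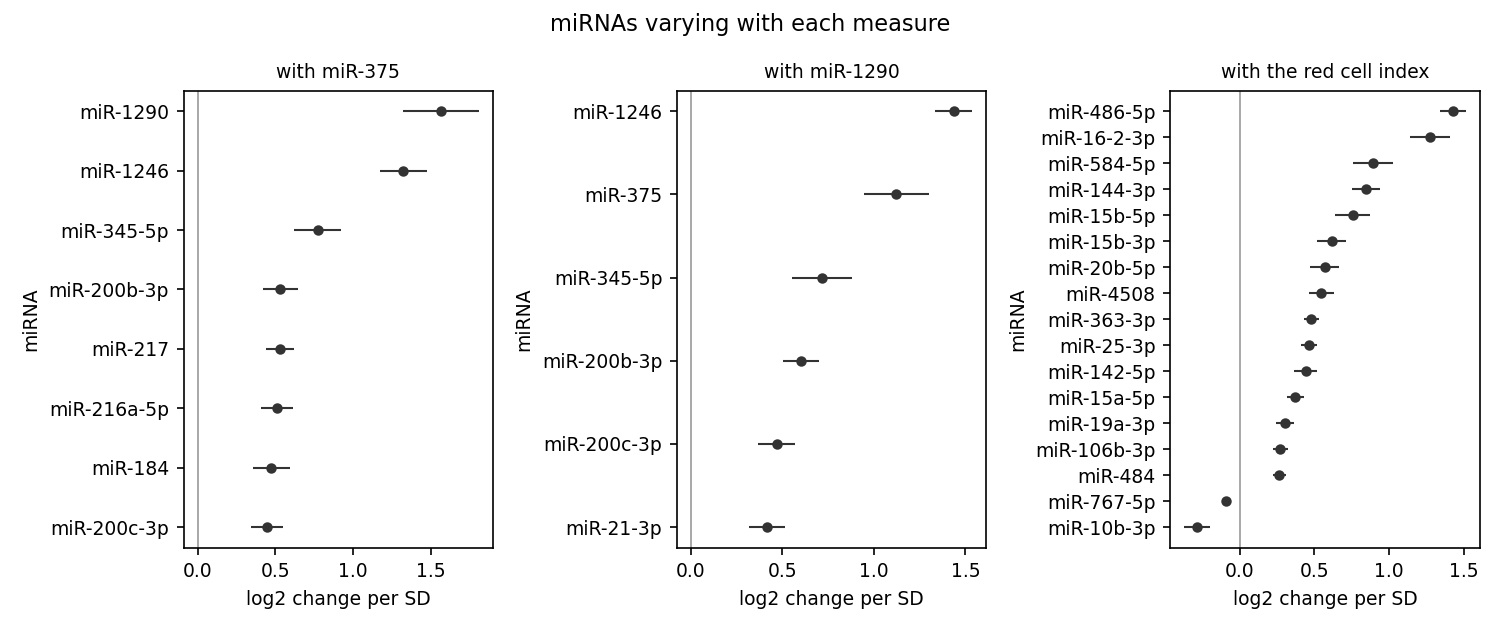
Log2 change per SD of miR-375, of miR-1290 and of the red cell index (x axis) for the miRNAs named by the rule (y axis); points are limma slopes over 23 libraries and bars are standard errors. The steepest rises are miR-1290 with miR-375 (1.57), miR-1246 with miR-1290 (1.44) and miR-486-5p with the red cell index (1.43).

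Known miRNAs held nearly the whole profile, and loci predicted to be miRNAs held little. The 56 predicted loci analysed took 3.12% ± 2.38 of the profile (SD, n = 23; 0.368% to 9.38%), and known miRNAs exceeded them by 5.38 ± 1.23 log2 units in 23 of 23 libraries (two-sided sign-flip permutation p = 1e-05, the smallest the permutations can give). The ratio compares totals of 375 known and 56 predicted rows, so its direction was favoured by the row numbers. Predicted loci varied far more, with a median SD of 1.94 against 0.30 log2 units for known miRNAs, and 27 of them stood at a floor in part of the libraries. Known miRNAs were listed only at a linear level of 1 or above in every library, and predicted loci also below it. The gap in spread may therefore come from the listing. The 3 most abundant lay on chromosome 6 from 27513468 to 27513544 (0.829% ± 1.19; at the floor in 8 libraries), on chromosome 6 from 28726140 to 28726212 (0.775% ± 1.26; 10 libraries) and on chromosome 15 from 65588389 to 65588470 (0.688% ± 1.72, or 0.408% ± 1.10 without its highest library; 10 libraries). Coordinates are as deposited, and the genome build is not given in the sources used here. Of the 431 rows, 11 held values identical to those of another row, 9 of them predicted loci, so part of the predicted loci cannot be separated.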

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

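Leaving out each library in turn, the library set as a factor or as removed means, rescaling to a common total, the added constant of 5 in the screens, the other candidate or the pseudogene share as a covariate, leaving out the 2 libraries of highest miR-375 in the list test, shares without the library with the highest value, class ratios over library set means, and detection at a linear level of 1 were chosen after the data were seen. Camera, adjustment over a list alone, tests between library sets and shuffled orders of a covariate were not planned either. Results that answer a comparison stayed on their side of the threshold, or within the allowed range, in 69 alternatives and left it in 17. Reversals were 0, and of the named miRNAs and lists 436 alternatives stayed and 83 lost the threshold. The 436 include shares without the highest library, all within 1 SD. These could not fail, since leaving out 1 library cannot move a mean by 1 SD of all libraries. The mean share of miR-375 still went from 0.0417% to 0.0220%. Among the 69, the median mature miRNA share and its mean without 1 library could not fail either. The mature miRNA share was 28.3% of query reads. Without the 3 most abundant miRNAs, the next 10 held 46.2%. Of 6 co-varying lists 3 passed among miRNAs at a linear level of 10 or more, where the candidate and epithelial lists were too short to test and liver did not pass, and 3 with depth and the red cell index regressed out. For the red cell list the latter says little, since the index is built from one of its members. Of the 8 calls with miR-375, 6 with miR-1290 and 30 with the red cell index, 2, 2 and 19 were left at a linear level of 10 or more in every library, where fewer miRNAs were tested. By rank the counts were 6, 3 and 4, and without the 2 most extreme libraries 6, 2 and 2. With the red cell index as a covariate they were 18 with miR-375 and 10 with miR-1290, given the other candidate 1 and 1, and given the pseudogene share 3 and 1. The cause was not tested. Leaving out each library gave 6 to 12, 4 to 9 and 11 to 33 calls, the 11 without the library of highest index. Of the main calls at least 4 of 8, 4 of 6 and 11 of 30 were kept. No count per miRNA was used, so the DESeq2 test and size factors, TMM, thinning and count filters were not run, nor total miRNA counts as a reference; depth behind single miRNAs is unknown. No paired analysis was possible because there is 1 group.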

Other observations

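The arms of a hairpin, the 5p and 3p strands cut from one precursor, kept a fixed order in most miRNAs. Of 92 hairpins with both arms listed, the 5p arm was higher in every library for 39 and the 3p arm in every library for 42. The widest gap was that of miR-99a-5p, 12.62 log2 units above its partner, and among hairpins with the 3p arm higher that of miR-378a, 1263-fold on the mean log2 scale, whereas for miR-9, a neural miRNA with abundant arms on both sides, the 3p arm was 1.89-fold higher, in 23 of 23 libraries. Arms of one hairpin varied together more than pairs matched on level (mean Spearman correlation 0.180 against 0.0363, one-sided p = 0.0010 over 2000 random pairings). For miR-9 it was 0.772. These hairpins were named after their values were seen.

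Leaving out the 2 libraries farthest from the median in the correlations, and the 2 of most extreme covariate in the screens, was fixed before the data were examined, but the limits for judging these were set afterwards. The other tests below were chosen after the patterns were seen; those on snRNA reads and on depth were set before their own results were seen. No biological explanation was tested, since the labels give no group among the patients.

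The first pattern is that miR-375, miR-1246 and miR-1290 varied together. That the 2 farthest libraries alone made it is argued against by the lowest r of the 3 pairs without them, 0.784. Other libraries with high miR-1290 stayed in, so a larger group of high libraries stays open. Library sets are argued against by the lowest partial r given the set, 0.888. With U2 snRNA genes and pseudogenes the miR-1246 hairpin shares 19 bases exactly and 22 with at most 1 mismatch, and that of miR-1290 12 and 19. Reads of U2 snRNA are argued against only where such reads fall in the snRNA class. Within sets r with the log2 snRNA share was -0.30 for miR-1246 and -0.27 for miR-1290 (n = 23, permutation p = 0.26 and 0.30). The rho was -0.20 and -0.24 (permutation p = 0.430 and 0.371), and the upper 95% bound of the higher r was 0.243. Reads of U2 pseudogenes stay open for miR-1246 and miR-1290, since the lower of their r with the log2 pseudogene share within sets was 0.713 but miR-375, whose hairpin shares no more than 9 bases with U2 at 1 mismatch, rose as closely (0.783). Reads shared between hairpins may add to the correlation of miR-1246 with miR-1290, since they share 17 bases with at most 1 mismatch, a length that 0 of 1877 other hairpins reach against miR-1246, but this leaves miR-375 unexplained.

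The second pattern is that erythroid miRNAs varied together. RNA of red cells remains a candidate explanation, since of the 8 red cell list rows other than miR-486, miR-16-2-3p and miR-144, 4 rose with the index and 0 fell; the abundant miR-16-5p did not pass (0.11 ± 0.04 per SD, limma adjusted p = 0.130). For miR-486-5p, miR-16-2-3p and miR-144-3p a few extreme libraries are argued against, since without the 2 most extreme the lowest of their slopes was 3.16 times its standard error, although miR-144-3p lost its call. For the other 25 rises this stays open, since their median slope per log2 unit went from 0.28 ± 0.06 (SE) to 0.13 ± 0.10 and 21 of 25 stayed positive.

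The third pattern is that RNA class shares differed between library sets. For snRNA, sequencing depth is argued against, because 93.8% of the variance of its share still lay between sets after regression on log10 mappable reads (permutation p = 0.0005, 2000 permutations). The other classes were not tested against depth. The snRNA share was 1.29% to 1.53% in libraries with 1-digit numbers in their titles and 0.565% to 0.903% in the others. What the title numbers stand for is not given. Differences in library preparation or pooling and differences between patients therefore stay open, since the labels tie neither to a set.

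The neural and endocrine list did not stand apart in steadiness: its median SD without miR-375 was at percentile 64.4 of matched random lists, and at 46.5 within library sets. Smooth muscle and stroma lay at percentile 8.39, and the candidates, red cell, liver and let-7 lists at 99.7 or above.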
